A study of Homo sapiens and Mus musculus with 62 samples.

How the data were processed

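RNA was measured in 62 libraries: 24 of CD34+ umbilical cord cells, 24 of HUDEP2 cells, 6 of K562 cells and 8 of mouse fetal livers. Per the labels' protocols, total RNA was made into stranded mRNA libraries. The deposited files hold counts of reads per gene. Per the submitters' processing notes, reads were aligned with HISAT2 2.1.0 to hg38 or mm10. Per the file headers, the authors counted them with featureCounts 1.6.4 (1.6.2 for K562) with strand option 2 on GENCODE 25 for human and M12 for mouse genes. Near-identical genes, such as HBA1 and HBA2 or the histone genes, may lose or share reads at this step, and replication-dependent histone transcripts mostly lack the poly(A) tail that mRNA kits select. The files hold no names, so human genes were named from GENCODE 29, which named 57388 of 57992 IDs and left 604 without a name. The 49585 mouse IDs had no table of names and are given as IDs with coordinates.

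Depth ran from 0.993 to 165 (in units of 1e6 assigned counts) per library. Pairs of libraries in a group were checked for duplicates by the chi-square per degree of freedom of their difference over genes with at least 20 counts. The 4 pairs at day 8 in CD34+ cells gave 1.35 to 2.15, all other pairs of those groups 59.0 to 91.2, CD34+ pairs of later days 39.3 to 96.2, HUDEP2 pairs 2.63 to 92.3, K562 pairs 1.36 to 3.16 and fetal liver pairs 4.42 to 34.2. A limit of 2.5, with a gap of at least 10 times to the other pairs of the group, was set after these values were seen, and the counts of the 4 pairs were summed.

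Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by group (minimum count 10, minimum total 15), TMM scaling, and quasi-likelihood F tests with Benjamini-Hochberg adjustment over the genes tested, called at an adjusted p under 0.05. CD34+ cells were fitted together in 10 groups of day and genotype, HUDEP2 cells in 8, and K562 and fetal livers each in 2. Compared were KD with WT on each CD34+ day, shRNA5 with control on each HUDEP2 day, KO with WT in K562 and fetal liver, and the last with the first day of CD34+ WT and HUDEP2 control cells. Differences of these effects between days were tested as interactions. Standard errors were derived as the absolute log2 fold change over the square root of F. These comparisons, tests, 27 gene lists and most alternatives were chosen before the data were examined.

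Lists were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists of a comparison with at least 5 tested members. Of 298 such tests 176 passed. By comparison, 15, 13, 17, 15 and 13 of 27 lists passed at CD34+ days 8 to 16, 11, 18, 16 and 14 of 22 at HUDEP2 days 0 to 7, 11 of 26 in K562, 17 of 27 in CD34+ WT and 16 of 22 in HUDEP2 control. Maturation sets were the 200 genes with the largest rise and the 200 with the largest fall between the first and last day of CD34+ WT or HUDEP2 control cells, at an adjusted p under 0.05 and a mean of at least 5 CPM.

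Genes named in each comparison were HEMGN, the 4 largest rises and 4 largest falls among protein-coding genes that passed, with a mean of at least 5 CPM and all libraries of one group above all of the other, and the 2 members with the lowest adjusted p of each list, at most 16 in all. The comparisons between days used 3, 3 and 10. Genes that could describe a donor, among them those of the Y chromosome and HLA, were left out by name. A few results that the rule selects are withheld and not reported here. Where a group had no counts, the bound on a fold change is taken from 3 counts per library, and ratios with 1 to 3 counts carry a 95% interval. These bounds and intervals cover counting error only.

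The procedure was tested on simulated data, with 200 genes changed 2-fold or 4-fold at the depths of the real libraries. It recovered 1% and 34% of them with 2 false calls at CD34+ day 8, 0% and 30% with 0 false calls at day 16, 96% and 100% with 5 in HUDEP2 day 0, 100% and 100% with 10 in K562, and 100% and 100% with 13 in fetal liver. DESeq2 recovered 12% and 60% at CD34+ day 8 with 107 false calls, and 9% and 58% at day 16 with 47. Its false calls were 24 in HUDEP2 day 0, 2 in K562 and 34 in fetal liver. The simulation gave all libraries of a system 1 mean profile and 1 spread per gene. It therefore lacks any difference in spread between the real groups.

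Alternatives were DESeq2 1.42.0, RLE or total-count scaling, removal of globin genes, no filter on low counts, fits of the 2 groups alone, the replicate number as a block, each library left out in turn and camera with an estimated correlation. Added after the data were seen were the day 8 libraries as separate replicates, WT libraries thinned to KD depth and a fit without the day 10 libraries. In fetal liver, samples with the same number deviated together in all 4 pairs (correlations 0.577 to 0.699). Another number correlated better in 3 of 4 cases (0.638, 0.724 and 0.684). Neither the data nor the labels therefore settle a pairing by number. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.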

Results

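Transcripts were counted in 62 RNA-seq libraries, made to ask which genes hemogen (HEMGN), a nuclear protein of red cell precursors, regulates as these cells mature. Of these, 54 were human. CD34+ umbilical cord cells cultured towards red cells gave 24 libraries, labelled wild type (WT) or knockdown (KD), with 4 per genotype at day 8 and 2 per genotype at days 10, 12, 14 and 16. HUDEP2, an immortalised erythroid progenitor line, gave 24 libraries, 3 of control cells and 3 of cells carrying a hairpin named shRNA5 at each of days 0, 3, 5 and 7 of induced differentiation. The labels give day 0 for libraries whose deposited files are named as day 1, so whether these precede induction rests on the labels. K562, an erythroleukemia line, gave 3 WT and 3 hemogen knockout (KO) libraries, and mouse fetal livers at embryonic day 14.5 gave 4 WT and 4 hemogen KO libraries.

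Depth differed widely between systems. Assigned counts per library, in units of 1e6, ran from 91.4 to 165 at day 8 in CD34+ cells, from 33.29 to 73.4 in WT at later days, and from 0.993 to 21.6 in the labelled KD at later days. HUDEP2 libraries held 15.6 to 56.9, K562 libraries 14.0 to 17.1 and fetal liver libraries 17.6 to 51.7 of these units. At day 8, libraries 1 and 3 of each genotype, and likewise 2 and 4, differed by little more than sampling noise, with a chi-square per degree of freedom of 1.35 to 2.15 against 59.0 to 91.2 for the other pairs. Each such pair was counted as 1 sample, which left 2 per genotype. All K562 WT pairs (1.36, 1.65 and 1.94) lay within the range of the merged pairs, and K562 KO pairs ran from 1.79 to 3.16. No K562 pair stood apart from the others of its group, as the rule for merging requires, so these libraries were kept separate. They may still be repeat libraries of 1 sample. Nothing in the labels says that replicates came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical.

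HEMGN (ENSG00000136929, hg38 chromosome 9, 97926791 to 97944856, minus strand) was read first, since it checks the labels. In K562 it was nearly lost, at 0.827 ± 0.119 CPM in KO against 277 ± 12.2 in WT (SD, n = 3; log2 fold change −8.37 ± 0.09 SE; edgeR adjusted p = 2.33e-40). In HUDEP2 shRNA5 it fell on each day, by 1.29, 2.25, 1.67 and 1.12 on the log2 scale at days 0, 3, 5 and 7, with edgeR adjusted p from 1.15e-10 to 1.84e-06. In CD34+ cells it passed the test at day 12 alone, at 69.1 ± 2.06 CPM in KD against 487 ± 130 in WT (SD, n = 2; log2 fold change −2.82 ± 0.50 SE; edgeR adjusted p = 0.014). That call was lost with WT 1, KD 1 or KD 2 of day 12 left out (edgeR adjusted p = 0.18, 0.0733 and 0.106), with the 2 groups fitted alone (0.119) and with the replicate number as a block (0.149), while the log2 fold change stayed between −3.07 and −2.52. At days 8, 10, 14 and 16 the log2 fold changes were −0.30, −1.69, −0.87 and −0.67, with edgeR adjusted p of 1, 0.188, 0.435 and 0.436. The first KD library of day 10 had 0 HEMGN counts among 0.993 x 1e6, which allows up to 3 counts. For these days the CD34+ groups are therefore called labelled KD throughout.

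**Figure D1:**
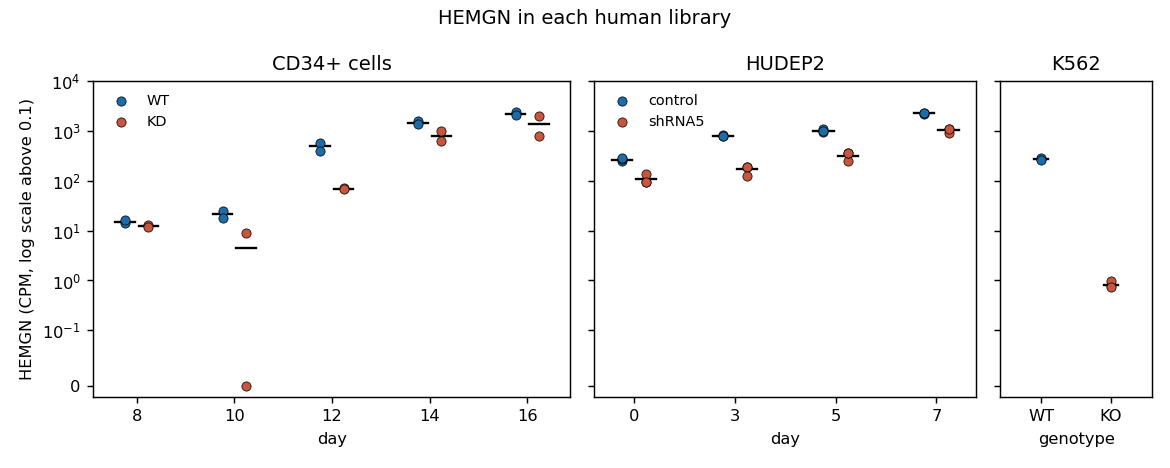
HEMGN in CPM (log scale above 0.1, linear below) for each human library by day or genotype, with blue points for WT or control, red points for KD, shRNA5 or KO, and a black line at each group mean. The K562 KO libraries sit near 0.827 CPM against 277 CPM in WT, and the 2 labelled KD libraries of CD34+ day 16 lie at 2000 and 781 CPM.

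The change of WT CD34+ cells from day 8 to day 16 gave the course of maturation against which the labelled KD could be read. HEMGN rose by 7.19 on the log2 scale, from 15.1 to 2210 CPM. All 10 globins rose, with a median log2 fold change of 10.51, and so did 29 of 31 red cell membrane genes (median 4.91), led by SLC4A1, the band 3 anion exchanger, at 16.90 ± 0.89 SE. Heme enzymes rose in 13 of 15 cases (14 adjusted over the list alone), among them ALAS2, the first enzyme of erythroid heme synthesis (10.51). ARG1, an arginase, rose with a ratio interval of 42020 to 1253000, PAQR9 was at least 11090-fold higher, and PLPP1, WNK3 and ENPP5 were at least 811-fold, 213-fold and 152-fold lower. Autophagy and terminal maturation genes rose in 22 of 25 cases (23 adjusted over the list alone), with XPO7, a nuclear export receptor, at 6.15 and ULK1, an autophagy kinase, at 5.99. Genes of the integrated stress response rose in 14 of 21 cases (15 adjusted over the list alone) and ribosome biogenesis genes fell in 20 of 25. In all, 4155 of 21307 genes passed edgeR's test, 2302 up and 1853 down (7597 with total counts as the only scaling, 1156 up and 6441 down), and each of these list changes passed camera with a preset and an estimated correlation (highest adjusted p = 0.00344). Mitosis genes, up in 17 of 25 cases with a median of 1.29, turned to 1 up and 2 down with a median of −0.03 when libraries were scaled by total counts alone. The count fell to 2215, 2227, 2241 and 2452 with WT sample 1 or 2 of day 8 or WT sample 1 or 2 of day 16 left out.

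At day 8, the progenitor stage, interferon-induced genes were higher in the labelled KD and some red cell membrane genes were lower, while HEMGN itself did not pass the test. IFI6 stood at 713 ± 457 CPM against 24.4 ± 3.13 (SD, n = 2; log2 fold change 4.87 ± 0.60 SE; edgeR adjusted p = 0.00119). ISG15, a ubiquitin-like protein, rose 16.9-fold, IRF7, a transcription factor of the interferon response, rose 8.46-fold and RSAD2, an antiviral enzyme, rose 6.85-fold. ANK1 and ADD2, which anchor the membrane skeleton, fell by 1.26 and 2.21 on the log2 scale, as did CDH1, the adhesion protein E-cadherin (−2.65), ESPN, an actin bundler (−1.86) and ERFE, the erythroid hormone that lowers hepcidin (−1.29). Of 24 interferon response genes, 3 passed the test over all genes and 22 adjusted over the list alone (median 2.93, camera adjusted p = 8.03e-75, and 0.000194 with an estimated correlation). Of 31 membrane genes, 2 fell, and 15 adjusted over the list alone (median −0.60, camera adjusted p = 2.84e-39, and 0.00051 with an estimated correlation). No globin passed over all genes, and 1 of 10 fell adjusted over the list alone, with a median of −0.68 (edgeR, camera adjusted p = 7.05e-13, and 0.00714 with an estimated correlation). Heme enzymes had a median of −0.46, with 3 of 15 lower adjusted over the list alone (camera adjusted p = 5.07e-16, and 0.00104 with an estimated correlation). Macrophage markers had a median of 0.97 (camera adjusted p = 0.000179, and 0.00714 with an estimated correlation). In all 15 genes passed edgeR's test, 8 up and 7 down, against 66 by DESeq2. That count fell with WT sample 1, WT sample 2 or KD sample 1 left out, but not with KD sample 2 left out. Each of these fits leaves 1 sample in a group, and most named genes of this day lost their call in at least 1 of them. The count was 1229 when the 2 groups were fitted alone, 845 of them up.

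By day 10, genes of heme synthesis, iron handling and the red cell membrane were lower in the labelled KD. ERFE stood at 17.9 ± 0.705 CPM against 113 ± 17.6 (SD, n = 2; log2 fold change −2.68 ± 0.23 SE; edgeR adjusted p = 1.61e-05). SLC25A37, which carries iron into mitochondria, fell by 2.00 on the log2 scale, and the heme enzyme ALAD by 2.18. KLF1 and EPOR, a transcription factor and the erythropoietin receptor that drive erythroid growth, fell by 1.63 and 1.72, and HBB fell 2.84-fold. TPSB2, a mast cell tryptase, rose 6.25-fold and IFI6 rose 11.9-fold. Heme enzymes fell in 9 of 15 cases (10 adjusted over the list alone; median −1.38, camera adjusted p = 9.75e-14, and 0.00247 with an estimated correlation), membrane genes in 12 of 31 (18 adjusted over the list alone; median −0.96, camera adjusted p = 1.97e-17, and 0.0126 with an estimated correlation) and iron genes in 4 of 20 (7 adjusted over the list alone; median −0.67, camera adjusted p = 6.39e-08, and 0.00247 with an estimated correlation). Of the other large changes, TAF3, PHF14 and LUC7L3 rose 38.2-fold, 15.5-fold and 13.9-fold with a KD spread larger than the mean, and IL18BP, EPN2 and KLHDC8A fell (−5.79, −4.84 and −3.87). Mitosis genes fell in 1 of 25 cases (12 adjusted over the list alone; median −0.80, camera adjusted p = 1.07e-08, and 0.101 with an estimated correlation). Mitochondrial transcripts fell in 3 of 13 cases (7 adjusted over the list alone, camera adjusted p = 6.55e-08, and 0.16 with an estimated correlation), led by MT-ND4L at −2.82. Mast cell, basophil and eosinophil markers had a median of 0.78, with 3 of 12 higher adjusted over the list alone (camera adjusted p = 2.81e-05, and 0.0481 with an estimated correlation). In all, 153 genes passed edgeR's test, 24 up and 129 down. The excess of falls hung on the method, with 53 up and 98 down by RLE factors, 199 up and 419 down without a filter and 518 up and 504 down by DESeq2. One KD library held 0.993 x 1e6 counts and the other 21.6 x 1e6. The count was 63, 48 and 2288 with WT 1, WT 2 or KD 2 left out, and 0 with the 2 groups fitted alone by edgeR (2409 at an unadjusted p under 0.05, and 1022 by DESeq2).

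At day 12, where HEMGN itself fell 7.04-fold, erythroid and mitotic genes were lower in the labelled KD and platelet lineage genes were higher. HBB stood at 3878 ± 856 CPM in KD against 17840 ± 5232 in WT (SD, n = 2; log2 fold change −2.20 ± 0.27 SE; edgeR adjusted p = 0.000738). SLC2A1, the glucose transporter of red cells, fell by 1.84, RRM2, a subunit of ribonucleotide reductase, by 1.93, KIF11 and MKI67, which act in dividing cells, by 1.64 and 1.28, ESCO2, a cohesin acetyltransferase, by 3.33 and DDIT4, a stress-induced inhibitor of mTOR, by 1.96. ALOX12, the platelet lipoxygenase, ITGA2B, the platelet integrin, and CLEC1B, a platelet receptor, rose 3.72-fold, 3.42-fold and 2.97-fold. IFI6 rose 8.87-fold and IL1RL1, the receptor for interleukin 33, rose 5.66-fold, whereas PAQR9 and PROSER3 fell by 2.91 and 2.81 and GALNT5, with 2 counts in KD, was lower by a ratio interval of 25.8 to 773. Membrane genes fell in 9 of 31 cases (24 adjusted over the list alone; median −1.06, camera adjusted p = 2.26e-18, and 0.0132 with an estimated correlation). Mitosis genes fell in 4 of 25 cases (24 adjusted over the list alone; median −1.25, camera adjusted p = 2.1e-17, and 0.0132 with an estimated correlation). Megakaryocyte markers rose in 2 of 17 cases (13 adjusted over the list alone; median 1.70, camera adjusted p = 7.68e-17, and 0.0258 with an estimated correlation). The KD libraries had 18.8% ± 3.42 mitochondrial counts against 11.8% ± 2.39 in WT (SD, n = 2). Mast cell, basophil and eosinophil markers had a median of 1.05, with 3 of 12 higher adjusted over the list alone (camera adjusted p = 3.33e-05, and 0.0337 with an estimated correlation). Most named genes of this day lost their call in at least 1 fit with a library left out. In all 150 genes passed edgeR's test, 24 up and 126 down, against 32 up and 41 down with RLE factors and 423 up and 623 down by DESeq2. The count was 19, 33 and 77 with WT 1, WT 2 or KD 2 left out, and 0 with the 2 groups fitted alone by edgeR (3457 at an unadjusted p under 0.05, and 1046 by DESeq2).

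At day 14 genes of late maturation were lower in the labelled KD. TMCC2, a membrane protein of late red cells, stood at 477 ± 1.12 CPM against 2886 ± 201 (SD, n = 2; log2 fold change −2.60 ± 0.26 SE; edgeR adjusted p = 0.000224). XPO7 fell by 1.81, BCL2L1, a survival factor, by 1.68, GABARAPL1, an autophagosome protein, by 1.63, GDF15, a secreted stress cytokine, by 1.51, HBB by 1.79 and HMOX1, heme oxygenase, by 2.62. Autophagy and terminal maturation genes fell in 7 of 25 cases (18 adjusted over the list alone; median −0.96, and −0.93 with zero-count members at their bound, camera adjusted p = 4.43e-19, and 0.000262 with an estimated correlation). Globins fell in 2 of 10 cases (6 adjusted over the list alone; median −1.33, camera adjusted p = 7.65e-06, and 0.0647 with an estimated correlation). Integrated stress response genes fell in 1 of 21 cases (10 adjusted over the list alone; median −0.72, camera adjusted p = 4.67e-07, and 0.0151 with an estimated correlation), the 1 being PPP1R15A at −1.22. Megakaryocyte markers had a median of 1.16, with 6 of 17 higher adjusted over the list alone (camera adjusted p = 1.23e-10, and 0.0604 with an estimated correlation). Mast cell, basophil and eosinophil markers had a median of 1.04 (camera adjusted p = 2.73e-05, and 0.0376 with an estimated correlation) and endothelial and stromal markers of 1.55, or 2.01 at the bound (camera adjusted p = 0.000287, and 0.0369 with an estimated correlation). Mitochondrial transcripts took 11.3% ± 2.02 of counts in KD and 5.48% ± 0.117 in WT (SD, n = 2). FOS and UHRF1BP1L were at least 34.0-fold and 26.2-fold lower, FANK1 was lower with a ratio interval of 24.4 to 5390, MMP9 and OAS3 were at least 251-fold and 87.6-fold higher, COL6A2 was higher with a ratio interval of 178 to 39800, and F2RL2 and MEF2C rose 19.5-fold and 10.6-fold. Most named genes of this day lost their call in at least 1 fit with a library left out. In all 110 genes passed edgeR's test, 20 up and 90 down, but 26 passed with total counts as the only scaling, 21 up and 5 down. The count was 2, 21, 32 and 4 with WT 1, WT 2, KD 1 or KD 2 left out, and 0 with the 2 groups fitted alone by edgeR (1926 at an unadjusted p under 0.05, and 1014 by DESeq2, 425 of them up).

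In the joint fit, which gives each gene 1 spread over all days, day 16 had the most calls of the CD34+ series. Nearly all of them were falls. With the 2 groups of a day fitted alone, day 8 had 1229 calls and day 16 had 0. This order of days therefore depends on the fit. The 2 labelled KD libraries differed in HEMGN, at 2000 CPM in KD 1 and 781 in KD 2, against 2353 and 2067 in WT. KD 1 thus lay close to WT in the targeted gene. Stress, autophagy and p53 target genes were lower in the labelled KD. TRIB3, a pseudokinase of the stress response, stood at 92.2 ± 32.2 CPM against 416 ± 16.2 (SD, n = 2; log2 fold change −2.17 ± 0.30 SE; edgeR adjusted p = 0.00199). SQSTM1, an autophagy receptor, fell by 1.56, ULK1 by 1.03, BBC3 and AEN, which p53 induces in dying cells, by 1.66 and 1.96, CEBPB by 1.43, the chaperones HSP90AB1 and HSPA5 by 1.49 and 1.38, HBB by 1.75 and EPB41, protein 4.1 of the membrane skeleton, by 1.26. FLI1, a megakaryocyte transcription factor, fell by 4.43 and CLEC1B, higher at day 12, was lower with a ratio interval of 6.31 to 1405. Megakaryocyte markers fell in 7 of 17 cases (9 adjusted over the list alone; median −2.76, and −2.23 at the bound, camera adjusted p = 0.000361, and 0.315 with an estimated correlation). UHRF1BP1L, MATN2, DOCK11 and AKAP7 had no counts in KD and were at least 19.3-fold, 16.4-fold, 16.1-fold and 14.2-fold lower. PNMT, LPCAT1, RADIL and ZNF155 rose 25.3-fold, 15.6-fold, 8.98-fold and 5.65-fold. Autophagy and terminal maturation genes fell in 11 of 25 cases (20 adjusted over the list alone; median −1.13, and −1.01 with zero-count members at their bound, camera adjusted p = 2.79e-10, and 0.003 with an estimated correlation). Integrated stress response genes fell in 5 of 21 cases (13 adjusted over the list alone; median −0.98, and −0.95 at the bound, camera adjusted p = 4.38e-06, and 0.0255 with an estimated correlation) and p53 targets in 6 of 20 (12 adjusted over the list alone; median −1.28, and −1.19 at the bound, camera adjusted p = 4.61e-06, and 0.0345 with an estimated correlation). Membrane genes fell in 7 of 31 cases (8 adjusted over the list alone; median −0.56, camera adjusted p = 0.0436, and 0.432 with an estimated correlation), but none did and the median was 0.07 with total counts as the only scaling. Mast cell, basophil and eosinophil markers had a median of 0.95, or 0.99 at the bound, with 1 of 12 higher (camera adjusted p = 9.39e-06, and 0.0436 with an estimated correlation). Mitochondrial transcripts took 9.10% ± 2.43 of counts in KD and 3.097% ± 0.0486 in WT (SD, n = 2). Most named genes of this day lost their call in at least 1 fit with a library left out. In all 864 genes passed edgeR's test, 36 up and 828 down, and the median of all tested genes was −0.70. With total counts as the only scaling 310 passed, 134 up and 176 down. The count was 126, 102 and 2352 with WT 1, WT 2 or KD 1 left out, and 0 with the 2 groups fitted alone by edgeR (2103 at an unadjusted p under 0.05, and 1920 by DESeq2, 536 of them up).

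Across the 5 CD34+ days, IFI6 was called higher on every day, while HBB, SLC25A39, a mitochondrial carrier, and SLC2A1 were called lower on at least 4 days. The labelled KD differed from WT by amounts that depended on the day for 214 genes by edgeR's test of the interaction (2787 at an unadjusted p under 0.05). That count ran from 28, with WT 2 of day 16 left out, to 1793, with KD 2 of day 10 left out, and was 0 with the replicate number as a block (2047 at an unadjusted p under 0.05, with no DESeq2 value). Autophagy genes had a median of 0.10 at day 8 and −1.13 at day 16, and integrated stress response genes 0.31 and −0.98. These differences between the first and last day passed camera (adjusted p = 6.75e-09 and 1.42e-08, and 0.00519 and 0.00645 with an estimated correlation). Interferon genes had medians of 2.93 and 0.06 (adjusted p = 2.65e-05, and 0.185 with an estimated correlation).

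**Figure D2:**
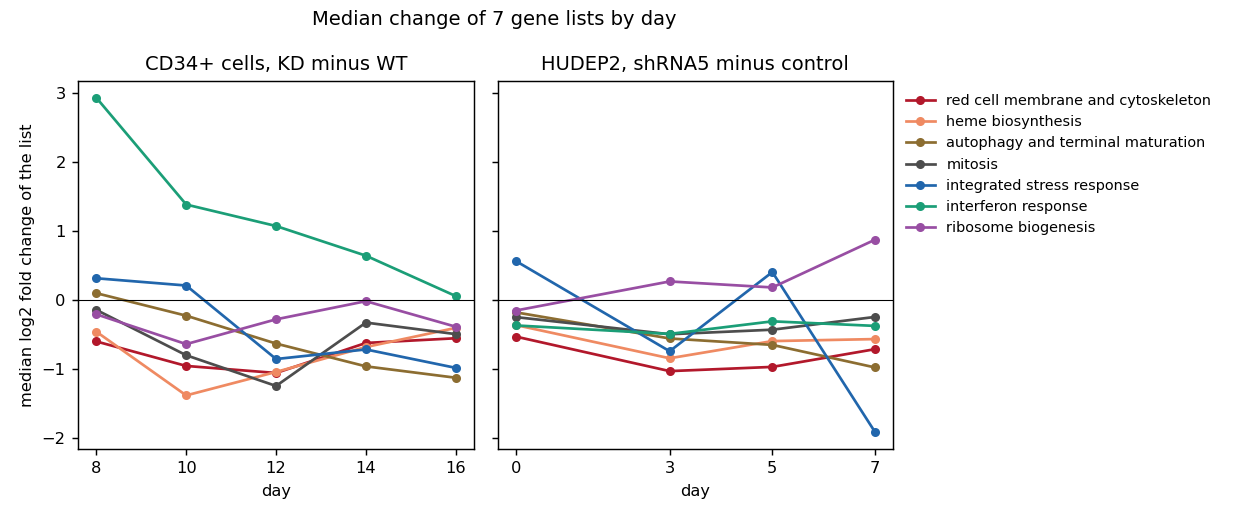
Median log2 fold change of 7 gene lists by day, KD minus WT in CD34+ cells (left) and shRNA5 minus control in HUDEP2 (right), where each point is the median over the tested members of a list and the line at 0 marks no change. Interferon genes started at 2.93 in CD34+ cells, and integrated stress response genes went from 0.57 at day 0 to −1.91 at day 7 in HUDEP2.

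Control HUDEP2 cells from day 0 to day 7 gave the corresponding change over induced differentiation in a line. HEMGN rose 8.38-fold, from 266 to 2235 CPM. Of 31 membrane genes 28 rose (29 adjusted over the list alone; median 1.96), as did all 15 heme enzymes (median 1.67), 23 of 24 autophagy genes (median 1.72) and all 20 integrated stress response genes (median 3.12), led by TRIB3 at 7.76 and ATF3 at 5.87 on the log2 scale. The rise of TRIB3 was not steady, at 68.49 to 74.68 CPM in control libraries at day 3, 14.65 to 17.22 at day 5 and 2090 to 2306 at day 7. How much of the change to day 7 is maturation and how much a late stress response was not tested. H1F0, a linker histone of resting cells, rose by 7.53 and RASGRP3 by 8.42. All 25 ribosome biogenesis genes fell (median −1.78), with CSF2RB, a cytokine receptor of progenitors, at −6.28 and ITGA2B at −5.30. MT1F and TNFRSF8 had no counts at day 7 and were at least 89.7-fold and 69.99-fold lower, and MYO1G was lower with a ratio interval of 431 to 95010. Each of these lists passed camera with an estimated correlation (highest adjusted p = 0.000168), whereas globins, up in 8 of 10 cases, did so with the preset correlation only (adjusted p = 0.000129, and 0.152 with an estimated correlation). In all 10861 of 16510 genes passed edgeR's test, 5205 up and 5656 down, and 26.1% of calls were up with total counts as the only scaling. DNA replication genes, up in 23 of 30 cases with a median of 0.49, had a median of −0.03 under that scaling.

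At the labelled day 0, HUDEP2 cells with shRNA5 had lower red cell membrane genes and globins and higher stress response genes. SLC4A1 stood at 170 ± 13.8 CPM against 1073 ± 47.6 (SD, n = 3; log2 fold change −2.65 ± 0.10 SE; edgeR adjusted p = 6.59e-15). TRIM10, a membrane list member, fell by 2.57, ALAD and CPOX, enzymes of heme synthesis, by 1.38 and 0.97 and the globin HBM fell 5.65-fold. PHGDH, the first enzyme of serine synthesis, rose 11.1-fold, TRIB3 5.72-fold, STC2, a secreted stress glycoprotein, 17.1-fold, CD33, a myeloid receptor, 11.7-fold and SPI1, the myeloid transcription factor PU.1, 2.51-fold. Among the other large changes, the histone genes HIST1H1B and HIST1H4C and BIN1 rose by 4.55, 4.41 and 4.12, and HPGDS, TIMP3 and MT1M fell by 3.45, 3.07 and 2.87. Membrane genes fell in 23 of 31 cases (24 adjusted over the list alone; median −0.53, camera adjusted p = 1.37e-22, and 4.67e-05 with an estimated correlation) and heme enzymes in 8 of 15 (10 adjusted over the list alone; median −0.36, camera adjusted p = 2.59e-08, and 0.00205 with an estimated correlation). Globins fell in 8 of 10 cases (9 adjusted over the list alone; median −1.15, camera adjusted p = 1.65e-06, and 0.0927 with an estimated correlation). Integrated stress response genes rose in 16 of 20 cases (17 adjusted over the list alone; median 0.57, camera adjusted p = 1.37e-22, and 2.45e-05 with an estimated correlation), and granulocyte and monocyte markers in 5 of 7, the same number adjusted over the list alone (median 1.56, camera adjusted p = 3.65e-06, and 0.000824 with an estimated correlation). Mast cell, basophil and eosinophil markers fell in 6 of 6 cases (median −0.88, camera adjusted p = 7.66e-05, and 0.00267 with an estimated correlation). Mitochondrial transcripts took 3.45% ± 0.116 of counts against 2.46% ± 0.336 (SD, n = 3). In all 4467 of 16510 genes passed edgeR's test, 2144 up and 2323 down.

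At day 3 membrane, heme and autophagy genes were lower in shRNA5 cells, with HEMGN at 21.0% of control. SLC4A1 stood at 294 ± 7.59 CPM against 3849 ± 127 (SD, n = 3; log2 fold change −3.71 ± 0.11 SE; edgeR adjusted p = 3.33e-17), ALAS2 fell by 1.90, SLC25A37 by 1.89, E2F2, a cell cycle regulator of erythroblasts, by 1.83 and TAL1, an erythroid transcription factor, by 1.33. INSIG1, a sterol sensor partner, fell by 2.45 and ARG1, PCYT1B, PIK3IP1 and TMEM233 changed by −5.74, −4.28, −4.01 and −5.47. HEPH, a copper oxidase that handles iron, rose 14.4-fold, and AKR1C3, FAM162B and CREB3L3 rose 13.5-fold, 12.2-fold and 10.5-fold. Membrane genes fell in 29 of 31 cases (median −1.03, camera adjusted p = 5.49e-41, and 1.71e-06 with an estimated correlation), heme enzymes in 14 of 15 (median −0.84, camera adjusted p = 4.2e-16, and 5.97e-05 with an estimated correlation), autophagy genes in 20 of 24 (median −0.56, camera adjusted p = 1.58e-10, and 1.58e-05 with an estimated correlation) and cholesterol synthesis genes in 17 of 21 (median −0.83, camera adjusted p = 4.44e-13, and 1.26e-05 with an estimated correlation). The same numbers fell adjusted over the list alone. Genes of the integrated stress response, higher at day 0, fell in 13 of 20 cases (14 adjusted over the list alone; median −0.74, camera adjusted p = 1.05e-06, and 0.00488 with an estimated correlation), among them TRIB3 at −1.53. Iron genes fell in 10 of 20 cases and rose in 5 (median −0.18, camera adjusted p = 0.00659, and 0.023 with an estimated correlation), but their median was 0.00 with total counts as the only scaling. Granulocyte and monocyte markers rose in 4 of 7 cases and fell in 1 (median 1.70, camera adjusted p = 0.00502, and 0.0206 with an estimated correlation). Mitochondrial transcripts rose in 9 of 13 (camera adjusted p = 0.00258, and 0.269 with an estimated correlation) and took 3.48% ± 0.644 of counts against 2.13% ± 0.289 (SD, n = 3). In all 7413 genes passed edgeR's test, 3728 up and 3685 down.

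At day 5 membrane genes, heme enzymes and p53 targets were lower in shRNA5 cells. SLC4A1 stood at 1272 ± 122 CPM against 5714 ± 239 (SD, n = 3; log2 fold change −2.17 ± 0.10 SE; edgeR adjusted p = 9.65e-14). GDF15, CDKN1A, the p53-induced cell cycle inhibitor, HMOX1 and BPGM, the red cell enzyme that makes bisphosphoglycerate, fell (log2 fold changes −4.58, −3.37, −2.63 and −2.12), and BCL2L1 fell 4.28-fold. TMEM233, TIMP3 and PTPRF changed by −6.59, −5.11 and −4.40, whereas STC2, CTSE, a protease, SERPINF1 and FAM162B rose 19.6-fold, 14.3-fold, 12.7-fold and 11.2-fold and ITGA2B rose 3.30-fold. Membrane genes fell in 26 of 31 cases (27 adjusted over the list alone; median −0.97, camera adjusted p = 7.57e-32, and 7.51e-06 with an estimated correlation), heme enzymes in 11 of 15, the same number adjusted over the list alone (median −0.60, camera adjusted p = 3.74e-09, and 0.00104 with an estimated correlation), and p53 targets in 10 of 18, the same number adjusted over the list alone (median −0.59, camera adjusted p = 5.33e-09, and 3.49e-05 with an estimated correlation). Integrated stress response genes rose in 9 of 20 cases and fell in 4 (9 and 5 adjusted over the list alone; median 0.40, camera adjusted p = 0.0415, and 0.168 with an estimated correlation), with PSAT1, an enzyme of serine synthesis, at 1.82. Granulocyte and monocyte markers rose in 3 of 7 cases (median 1.16, camera adjusted p = 0.0179, and 0.0499 with an estimated correlation). Mitochondrial transcripts rose in 10 of 13 (camera adjusted p = 4.28e-05, and 0.149 with an estimated correlation) and took 3.50% ± 0.544 of counts against 1.77% ± 0.0289 (SD, n = 3). In all 5980 genes passed edgeR's test, 3001 up and 2979 down.

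At day 7 stress response genes, which were higher in control cells at day 7 than at day 0, were lower in shRNA5 cells than in control. TRIB3 stood at 75.2 ± 1.97 CPM against 2225 ± 118 (SD, n = 3; log2 fold change −4.89 ± 0.10 SE; edgeR adjusted p = 5.14e-20). ATF3, a stress-induced transcription factor, fell by 3.86, GDF15 changed by −5.83, CDKN1A by −4.54, TNFRSF10B, a death receptor, by −3.40, MAP1LC3B, an autophagosome protein, by −2.65 and HSPA5, the chaperone of the endoplasmic reticulum, by −2.02. CLU, TMEM233, RASGRP3 and TSLP fell by 7.00, 6.40, 6.24 and 6.01. CTSE, AKR1C3, PDK4 and MRC2 rose 22.5-fold, 19.3-fold, 18.2-fold and 15.3-fold, and BID, a death promoter, rose 6.19-fold. Integrated stress response genes fell in 19 of 20 cases (20 adjusted over the list alone; median −1.91, camera adjusted p = 8.33e-46, and 2.71e-07 with an estimated correlation), p53 targets in 12 of 18 (median −0.87, camera adjusted p = 3.62e-11, and 9.68e-06 with an estimated correlation), autophagy genes in 19 of 24 (median −0.98, camera adjusted p = 5.61e-13, and 6.12e-06 with an estimated correlation) and membrane genes in 23 of 31 (median −0.71, camera adjusted p = 6.88e-09, and 0.00339 with an estimated correlation). The counts for these last 3 lists were the same adjusted over the list alone. Ribosome biogenesis genes rose in 23 of 25 cases, the same number adjusted over the list alone (median 0.87, camera adjusted p = 3.93e-10, and 0.00339 with an estimated correlation). Mitochondrial transcripts rose in 13 of 13 (camera adjusted p = 4.17e-10, and 0.0515 with an estimated correlation), and took 3.36% ± 0.161 of counts against 1.03% ± 0.0115 (SD, n = 3). Globins fell in 3 of 10 cases and rose in 1 (camera adjusted p = 0.821). In all 7989 genes passed edgeR's test, 4212 up and 3777 down.

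**Figure D3:**
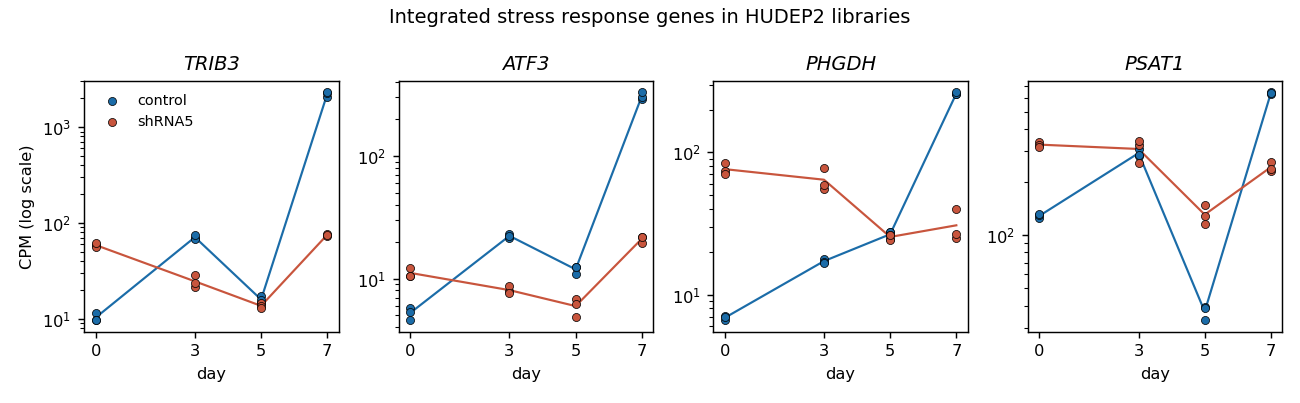
CPM on a log scale by day for TRIB3, ATF3, PHGDH and PSAT1 in HUDEP2, with blue points for control libraries, red points for shRNA5 libraries (n = 3 per group and day) and lines through the group means. At day 0 the shRNA5 libraries lie above control, with TRIB3 at 58.7 against 10.2 CPM, and at day 7 they lie below, at 75.2 against 2225 CPM. Control TRIB3, ATF3 and PSAT1 dip at day 5 before they rise at day 7, whereas control PHGDH rises on each day. In control library 1 TRIB3 lies at 69.48 CPM at day 3, 17.22 at day 5 and 2090 at day 7.

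Over the 4 HUDEP2 days, 627 genes were called higher and 798 lower in shRNA5 on each day. For 7054 of 16510 genes the difference depended on the day by edgeR's test of the interaction, and 1352 of those were called in opposite directions on different days. With total counts as the only scaling 71.0%, 69.4%, 74.2% and 70.6% of calls were up at days 0, 3, 5 and 7, against 48.0%, 50.3%, 50.2% and 52.7%.

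In K562 the question was what changes when HEMGN transcripts are nearly lost in a line that is not induced to mature. Eosinophil, basophil and neutrophil genes appeared in KO and platelet genes and globins were lower. CLC, the galectin of eosinophil and basophil granules, stood at 63.2 ± 0.452 CPM in KO and 0 in WT (SD, n = 3), at least 333-fold higher, and PLPP1 was at least 65.2-fold higher. EPX, eosinophil peroxidase, was higher with a ratio interval of 568 to 16960. CSF3R, the receptor for granulocyte colony-stimulating factor, rose by 7.78 ± 0.18 SE (edgeR adjusted p = 1.08e-29), CD33 by 3.29, SPI1 by 3.21 and DLK1, a progenitor surface protein, by 2.75. RAB27B, which moves platelet granules, fell by 5.36, TUBB1, the platelet tubulin, by 2.52, the globins HBD and HBE1 by 3.29 and 1.84, and the red cell genes CA1 and STOM by 3.85 and 1.91. PLOD2, TRDN and NNMT fell by 7.21, 6.38 and 6.20, and ABLIM1 was lower with a ratio interval of 67.1 to 957. Granulocyte and monocyte markers rose in 12 of 13 cases (median 3.57, camera adjusted p = 3.6e-14), mast cell, basophil and eosinophil markers rose in 5 of 7 and fell in 2 (median 3.63, camera adjusted p = 2e-09) and megakaryocyte markers fell in 8 of 9 (median −2.23, camera adjusted p = 7.79e-11), each with an adjusted p of 0.0271 with an estimated correlation. Globins fell in 8 of 9 cases (median −0.91, camera adjusted p = 3.6e-14, and 0.108 with an estimated correlation) and membrane genes in 18 of 27 (median −0.36, camera adjusted p = 1.07e-07, and 0.0561 with an estimated correlation). The same numbers passed adjusted over the list alone. Mitochondrial transcripts fell in 13 of 13 cases (median −0.52, camera adjusted p = 2.95e-05, and 0.461 with an estimated correlation) and took 3.31% ± 0.322 of counts in KO against 4.11% ± 0.0622 in WT (SD, n = 3). Heme enzymes rose in 5 of 15 cases and fell in 9, with no shift of the list (camera adjusted p = 0.241). In all 9583 of 15273 genes passed edgeR's test, 4814 up and 4769 down. K562 replicates lay close to sampling noise, so small changes pass, and 955 of the rises and 1054 of the falls were at least 2-fold. The WT replicates were as close as the CD34+ day 8 pairs counted as 1 sample, so p-values here may measure technical spread only.

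**Figure D4:**
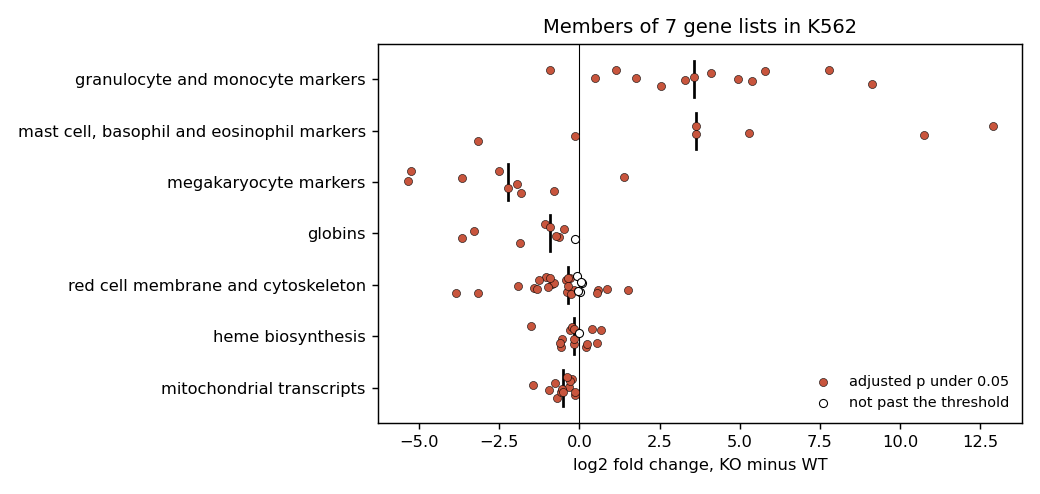
Log2 fold change, KO minus WT, of the members of 7 gene lists in K562, with filled points for genes at an edgeR adjusted p under 0.05, open points for the rest and a black bar at each list's median. Granulocyte and monocyte markers centre on 3.57 and megakaryocyte markers on −2.23.

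Fetal livers of hemogen KO mice differed from WT livers in a large share of transcripts. The deposited mouse tables pair no gene IDs with names, so results are given by ID, and which ID is the targeted gene was not looked up. An ID given below as lower in KO may therefore be the targeted gene itself. ENSMUSG00000054146 (mm10 chromosome 11, 100131758 to 100135928) had 2346 counts in KO and 2 in WT, a ratio of 713 with a counting interval of 197 to 5892, and ENSMUSG00000020908 (chromosome 11, 67078300 to 67102291) stood at 121 ± 4.85 CPM in KO against 0.234 ± 0.0908 in WT (SD, n = 4; log2 fold change 9.10 ± 0.10 SE; edgeR adjusted p = 1.62e-13). ENSMUSG00000083773 (chromosome 2, 28933610 to 28934609) changed by −8.02 and ENSMUSG00000028332 (chromosome 4, 46393989 to 46413506) by −5.72. Of 20 mitochondrial genes 9 rose and 2 fell, with mitochondrial counts at 10.5% ± 0.419 in KO against 6.62% ± 0.62 in WT (SD, n = 4). In all 10626 of 16230 genes passed edgeR's test, 5478 up and 5148 down. Changes of at least 2-fold made up 1532 and 1150 of them. With total counts as the only scaling 70.3% of calls were up against 51.6%.

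Genes that changed most over differentiation in one system were then followed in the others, with no library shared between a gene set and its test. The sets take the whole change from first to last day, so the HUDEP2 rising set also holds stress genes such as TRIB3. The 200 genes that rose most in maturing CD34+ WT cells fell in HUDEP2 shRNA5, in 71, 130, 134 and 117 of 176 tested at days 0, 3, 5 and 7 (camera adjusted p = 4.19e-10, 1.18e-52, 6.08e-57 and 7.56e-26, and 0.0252, 2.9e-05, 2.9e-05 and 0.00116 with an estimated correlation). In K562 KO 58 of 129 fell and 41 rose (camera adjusted p = 0.00219, and 0.0432 with an estimated correlation). The 200 genes that fell most in CD34+ WT cells did not shift at HUDEP2 day 0 or in K562 (camera adjusted p = 0.325 and 0.322). They were higher in shRNA5 at days 3, 5 and 7 (camera adjusted p = 5.24e-06, 0.000163 and 0.0148, and 0.0111, 0.0252 and 0.103 with an estimated correlation). The 200 genes that rose most in maturing HUDEP2 control cells had medians of 0.17 and −0.17 in the labelled CD34+ KD at days 8 and 10 (camera adjusted p = 7.53e-05 upward and 0.672, and 0.104 and 0.845 with an estimated correlation), and were lower at days 12, 14 and 16, with medians of −0.87, −0.77 and −0.98 over 199 tested (camera adjusted p = 1.14e-06, 5.46e-13 and 1.21e-08, and 0.0607, 0.0194 and 0.0307 with an estimated correlation). The 200 genes that fell most in HUDEP2 control cells were higher in the labelled KD at days 12 and 14 (camera adjusted p = 1.66e-19 and 1.37e-12, and 0.0202 and 0.0442 with an estimated correlation). At days 10 and 16 they passed upward with the preset correlation only (0.122 and 0.352 with an estimated one), and at day 8 they did not (0.622). When each library was placed between the first and last day of its own unperturbed cells, by genes chosen in the other system, control HUDEP2 cells reached 34.8% ± 0.62 at day 3, 53.3% ± 0.98 at day 5 and 100% ± 1.02 at day 7, and shRNA5 cells 6.44% ± 0.84, 28.3% ± 0.97 and 75.3% ± 0.59 (SD, n = 3). The differences were −28.3, −25.0 and −24.7 points, each with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow, and −4.36 points at day 0 with the same p. In CD34+ cells the labelled KD stood at 2.93%, 11.1%, 31.2%, 66.5% and 88.9% at days 8 to 16 against 0%, 22.0%, 52.0%, 84.5% and 100% in WT, with an SD of 16.5 points in KD at day 16 and n = 2 throughout. At day 16 KD 1 lay at 100.5%, level with WT, and KD 2 at 77.2%, so the lower mean rests on 1 library.

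**Figure D5:**
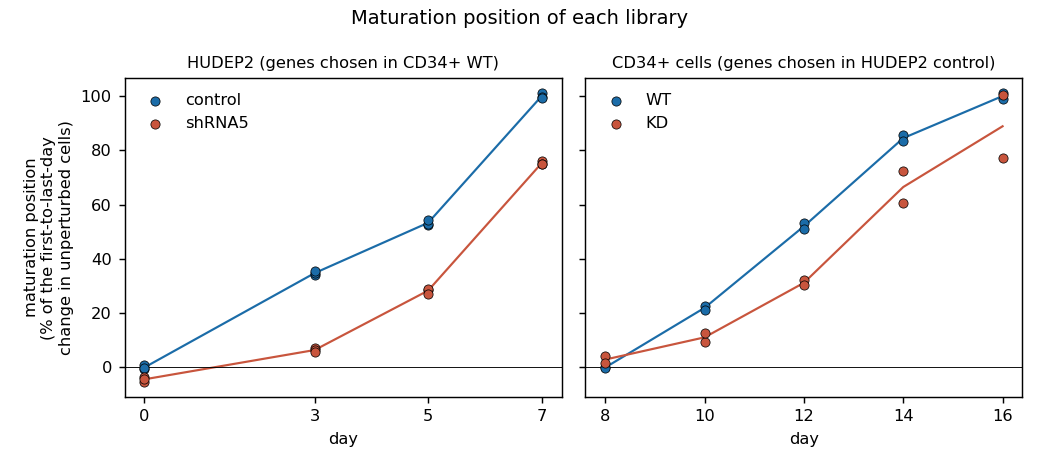
Position of each library, in percent of the change between the first and last day of unperturbed cells, by day for HUDEP2 (left, genes chosen in CD34+ WT) and CD34+ cells (right, genes chosen in HUDEP2 control), with blue for control or WT, red for shRNA5 or KD, points for libraries and lines through group means. HUDEP2 shRNA5 libraries reach 75.3% at day 7, where control libraries reach 100%.

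Calls shared between systems were compared with the numbers that independent lists would give. HUDEP2 day 0 and K562 shared 661 genes called up, against 538 by chance, and 745 called down, against 640. Opposite calls also exceeded chance among genes called down in HUDEP2 and up in K562, at 730 against 664. HUDEP2 day 7 and K562 shared 1346 up, against 1201 by chance, and 1088 down, against 1019, but opposite calls exceeded chance too, at 1210 against 1158 for genes up in HUDEP2 and 1189 against 1056 for genes down in HUDEP2. All 6 tested genes called down at day 8 in CD34+ cells were also down in K562 KO, against 1.8 by chance, and 5 of 7 were down in HUDEP2 at day 0, namely ADD2, ERFE, ANK1, AHSP, a globin chaperone, and CDH1, against 1 by chance. Of the 8 genes called up at CD34+ day 8 by edgeR, 2 were up and 4 down at HUDEP2 day 0 (1 and 1.1 by chance), and 0 up and 7 down at day 7 (2.1 and 1.8 by chance). Of 26 called up by DESeq2, 10 were up at HUDEP2 day 0 (3.8 by chance) and 4 at day 7 (6.4 by chance). Of 7 tested in K562, 3 were up and 3 down (2.2 and 2.1 by chance). No p-value is given for these overlaps, because genes are not independent.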

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

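Results here stood out by 2 rules: a sample far from the others of its group, or an effect that differed between days. The tests of interferon genes in other cells and at day 16, of another cell line, of scaling, and of depth as the whole source of falls were chosen after the result was seen.

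In fetal liver KO, 1 of 4 libraries lay apart in the share of counts held by its 10 most abundant genes, with a gap of 0.922 of the group's range, although that range spans only 24.94% to 25.7%. Of 16 tests of 8 measures in the 2 fetal liver groups this was the only one past the critical value, and chance marks about 1 in 20.

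In CD34+ cells the labelled KD effect differed between days for 214 genes by edgeR's adjusted p (28 to 1793 with 1 library left out, and 0 with the replicate number as a block), with 38 of the 85 named among them. By camera 11 lists differed between day 8 and day 16, and with an estimated correlation only 2 did. These were autophagy genes (adjusted p = 6.75e-09, then 0.00519) and integrated stress response genes (adjusted p = 1.42e-08, then 0.00645), which were near WT or higher at day 8 and lower at day 16. The platelet genes CLEC1B (edgeR adjusted p = 0.00829) and ALOX12 (edgeR adjusted p = 0.00969) and the mitochondrial transcript MT-ND4L (edgeR adjusted p = 0.0116) changed by amounts that depended on the day.

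In HUDEP2 the shRNA5 effect differed between days for 7054 genes, 61 of them among the 63 named, and 10 lists differed between day 0 and day 7. With an estimated correlation 5 of these did (highest adjusted p = 0.000746), and globins, apoptosis, glycolysis, heat shock and mitochondrial genes did not (0.424, 0.0708, 0.354, 0.354 and 0.194). By camera, integrated stress response genes (adjusted p = 2.83e-91), ribosome biogenesis genes (1.24e-13), p53 targets (3.62e-11), autophagy genes (1.39e-09) and genes of cell cycle arrest (1.98e-07) did so. Stress genes included TRIB3 (edgeR adjusted p = 6.74e-20), ATF3 (2.26e-15), the serine synthesis enzymes PHGDH (5.8e-16) and PSAT1 (7.53e-14), STC2 (5.8e-16), the chaperone HSPA5 (2.08e-12) and HMOX1 (1.6e-13). The rest were TNFRSF10B (edgeR adjusted p = 5.8e-16), TRIM10 (6.27e-15), the urea transporter SLC14A1 (9.91e-12), HIST1H4C (1.04e-11), the cell cycle inhibitor CDKN2B (2.69e-11) and BIN1 (5.4e-07).

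Falls outnumbered rises by far at CD34+ day 16, with 828 against 36. Thinning WT libraries to KD depth left 335 falls. Thinning also lowers power, so this drop cannot show that the depth gap produced the lost calls. Rises were still only 7.5% of calls, which depth alone would not leave. Scaling by total counts moved the median of all genes by 0.62 at day 16 and gave 43.2% rises. The imbalance therefore depends on the scaling, and which scaling is right was not tested. Of genes at 10 to 50 CPM in WT, 11.89% had no count in 1 of the 2 KD libraries, which may point to few distinct RNA molecules in those libraries.

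Interferon genes were higher in the labelled KD at CD34+ day 8. All 24 lay above both WT samples even in the KD sample with fewer of them, against a rise carried by 1 library. The highest median of the list over HUDEP2 and K562 was −0.28 (−0.277), against a general effect of lower hemogen in erythroid cells. A response to vector delivery could not be told apart, since no arm is labelled vector-only and the labels do not say what WT cells received, and the median was 0.06 (0.056) at day 16, where the list still passed camera upward (adjusted p = 0.00656, and 0.315 with an estimated correlation). The drop from day 8 passed with the preset correlation only (camera adjusted p = 2.65e-05, and 0.185 with an estimated one).

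Myeloid genes were higher in K562 KO. A difference between clones unrelated to hemogen would not be shared, yet genes up at least 8-fold in K562 were also higher in HUDEP2 shRNA5 at day 0, as 20 of 43 rose and 5 fell (camera p = 0.00138 with an estimated correlation) and at days 3 and 5 (p = 0.000825 and 0.00834), though not at day 7 (p = 0.266). On the 5 CD34+ days the set passed upward with the preset correlation (camera adjusted p from 2.75e-06 to 0.00628) but not with an estimated one (p from 0.0827 to 0.328), and mast cell, basophil and eosinophil markers, higher in K562 KO, fell in 6 of 6 cases at HUDEP2 day 0 (camera adjusted p = 0.00267 with an estimated correlation), so the sharing is partial. Another cell line in place of the KO cells would be expected to erase erythroid genes, but the median of membrane genes was only −0.36 (−0.364), a fall of 22.3% that leaves room for a minor admixture, of which no profile exists here. The sharing with HUDEP2 cannot count against a difference between clones, because the set was not compared with genes of similar expression. At HUDEP2 day 0 calls were 2144 up and 2323 down, but 1153 up and 1865 down at 5 CPM or more. Weaker genes thus tended to rise there, whether or not they belonged to the set. How many of the 43 tested genes were weak was not tested. A difference between clones, admixture, drift of the KO line and an effect of hemogen on lineage choice stay open.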

How the results depend on the processing

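HUDEP2, K562 and fetal liver counts of calls stayed within 1.5 times under each alternative, and no named gene turned its direction. No list turned its direction with an estimated correlation or the replicate block. Lists were not tested with camera under the other alternatives. Under other scalings some list medians changed sign, and HUDEP2 day 0 calls went from 2144 up and 2323 down to 3353 and 1371 with total counts. CD34+ counts did not stay within 1.5 times. With 2 samples per group and KD libraries down to 0.993 x 1e6 counts, only large changes can be called. Where a cause is not given below, the cause was not tested. Relative to TMM, RLE factors moved the median of all genes by 0.19, 0.21 and 0.34 at CD34+ days 10, 12 and 16, and total counts moved it by 0.62 at day 16, −1.32 for CD34+ WT, 0.13, 0.18, 0.20 and 0.24 at HUDEP2 days 0 to 7 and −0.52 for HUDEP2 control. With RLE factors the CD34+ calls were 73 (32 up, 41 down) at day 12, 64 (18 up) at day 14, 342 (48 up, 294 down) at day 16 and 134 for the interaction. With total counts they were 93 at day 12, 26 at day 14, 310 at day 16, 7597 (1156 up, 6441 down) in WT and 128 for the interaction. Removing globin genes gave 235 at day 12. Without a filter there were 69 at day 8, 618 (199 up) at day 10, 432 (152 up) at day 12, 326 (133 up) at day 14 and 673 for the interaction. DESeq2 gave 66, 1022 (518 up), 1046 (423 up), 1014 (425 up) and 1920 (536 up) at days 8 to 16, and was not run for the interactions. In simulated CD34+ data it made more false calls than edgeR. With only the 2 groups there were 1229 (845 up), 0, 0, 0 and 0 calls, and 11736 (4439 up) in WT. The spread then rests on 2 samples per group. Counts rose at day 8 and in WT, from 15 and 4155 in the joint fit, and fell to 0 on the other days. The cause was not tested.

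With the replicate number as a block, edgeR called 0 genes at day 8 (353 at an unadjusted p under 0.05, and 66 by DESeq2), 44 at day 10, 4 at day 12, 4 at day 14, 104 at day 16 and 0 for the interaction (2047 at an unadjusted p under 0.05; no DESeq2 value). Same-numbered samples correlated by −0.082 to 0.306 in CD34+ cells, −0.526 to 0.611 in HUDEP2 and −0.096 to 0.044 in K562, so a pairing by number was not shown. The block changed no other count by over 1.5 times, and in fetal liver it gave 10981.

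Chosen after seeing the data, day 8 libraries as separate replicates gave 150 calls at day 8, 9025 in WT and 2594 for the interaction. WT libraries thinned to KD depth gave 70 at day 14, 362 at day 16 (27 up, 335 down) and 123 for the interaction. Without the day 10 libraries day 12 had 276 calls.

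With each library left out in turn, a lone remaining sample is assumed to vary like the other groups. Counts ran from 5 to 17 at CD34+ day 8, 48 to 2288 at day 10, 19 to 108 at day 12, 2 to 32 at day 14, 102 to 2352 at day 16, 2215 to 2452 in WT and 28 to 1793 for the interaction. They ran from 3084 to 5684, 6235 to 7344, 4733 to 5702 and 7096 to 7788 at HUDEP2 days 0, 3, 5 and 7, 10068 to 10323 in control, 6365 to 7569 for the interaction, 9099 to 9413 in K562 and 10231 to 10605 in fetal liver.

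With an estimated correlation 90 list tests passed in place of 176, and 86 of 298 were weaker. Named genes that were weaker with a library left out were all in the CD34+ comparisons of KD with WT, where such a fit leaves 1 sample in a group. Most named genes lost their call in at least 1 such fit at days 8, 12, 14 and 16, and a smaller part did at day 10. No named gene of CD34+ WT, HUDEP2 or K562 lost its call. Of tests of named genes, 24 and 30 of 262 were weaker with RLE factors and total counts, 95 of 239 with only the 2 groups and 73 of 229 with the block. DESeq2 kept all 262. Of 26 up and 31 down calls at CD34+ day 8 by DESeq2, 10 and 14 were shared with HUDEP2 day 0 (3.8 and 4.5 by chance) and 4 and 16 with day 7 (6.4 and 7.8 by chance). Of 24 and 27 tested in K562, 8 and 18 were shared (6.7 and 7.1 by chance). By edgeR the shared counts were 2 and 5, 0 and 3, and 3 and 6.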

Other observations

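The delayed-maturation test and the test of a difference before induction were set before their values were seen, and the gene sets looked at in addition were chosen after.

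SWI/SNF genes, which code for the chromatin remodelling complex built around BRG1, passed camera in none of the 12 comparisons, with a lowest adjusted p of 0.078 at CD34+ day 16. Among HUDEP2 genes called in opposite directions on different days, 13 were named.

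Lower erythroid genes in HUDEP2 shRNA5 could come from delayed maturation. Of genes called at day 7, 64.0% (5109 of 7989) moved against the control change from day 3 to day 5, against 50% by chance. That window precedes the lag at day 7, where shRNA5 cells had a position of 75.3%, between control day 5 (53.3%) and control day 7 (100%). It scores genes whose control level dips at day 5 and rises at day 7, such as TRIB3, against delay. The remaining genes therefore cannot count against delay, and delay and a direct effect could not be told apart. The share was 64.4% (3742 of 5807) among genes at 5 CPM or more, and 70.7% (979 of 1384) among those also called between control days 3 and 5. The day 0 difference in position was 17.6% of that at day 7, so the difference in position at the labelled day 0 does not cover most of the lag. This score cannot exclude another difference between the 2 populations as its source, since 4467 genes already differed at the labelled day 0. That this day precedes induction rests on the labels, since the deposited files name it day 1.

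Whether any other grouping of the samples gives as many calls was tested with all other splits of the same libraries. In HUDEP2 the real splits gave 4467, 7413, 5980 and 7989 calls at days 0, 3, 5 and 7, and the highest other splits 1, 1, 0 and 2. The control change gave 10861 against 0 and K562 9583 against 0. In each only 1 split, the real one, gave as many, but 10 splits are too few for a share under 0.05. Beside the 0 calls, edgeR's highest other splits held 1907, 295 and 107 genes at an unadjusted p under 0.05 for day 5, the control change and K562. In fetal liver the real split gave 10626 calls and was the only 1 of 35 splits to give as many (share 0.0286). The highest other gave 253, and it set samples 1 and 2 of both genotypes against the rest. Of the 8 splits that part all 4 same-numbered pairs, the real one included, the others gave 0 calls by edgeR (at most 481 genes at an unadjusted p under 0.05, DESeq2 not run on these splits). These 8 splits are too few for a share under 0.05, and whether same numbers mark true pairs is not settled.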
